A study of Mus musculus with 44 samples.

How the data were processed

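The samples were haematopoietic stem cells (HSC) of C57BL/6 mice, sorted from bone marrow as Lineage- Sca-1+ c-kit+ CD34- cells. Fus encodes an RNA-binding protein, and mice carrying a Fus-gfp fusion allowed these cells to be sorted by green fluorescence into Fus low and Fus high fractions. The series lists 44 samples. RNA was sequenced from 9 Fus low and 9 Fus high libraries, made from 100 cells each by the Smart-seq2 full-length method. A first ageing set held 3 young and 3 aged RNA libraries, and a new set held 3 young, 3 aged and 3 aged Fus knockdown RNA libraries. Young animals were 2 months old and aged animals 30 months old. Binding of CTCF, the architectural protein that anchors chromatin loops, was mapped by CUT&RUN in 1 young and 1 aged library made from 100000 cells, and by CUT&Tag in 2 Fus high and 2 Fus low libraries. Both assays release or tag DNA around an antibody-bound protein. Chromatin contacts were mapped by Hi-C; the protocol, written for the Fus fractions, used 20000 cells and digestion with MboI, and no cell number is given for the aged library. The labels do not say how Fus was knocked down, what the numbers 30, 32 and 36 in the names of the Fus RNA libraries stand for, or which animals gave which library. The 4 Hi-C samples of the Fus low and Fus high fractions (2 each) were not analysed here.

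For the Fus RNA libraries the authors deposited counts per gene symbol for 24421 genes, made with HTSeq, and a table of TPM for 24277 genes whose 18 columns were all matched to a library. The submitters' processing notes name HISAT2 2.2.1, HTSeq 0.11.1, DESeq2 1.26.0, HiC-Pro, SEACR and the mouse build mm10, without parameters. Counts are raw, and the Smart-seq2 method carries no molecular identifiers, so amplified copies of 1 molecule count as separate reads. For the ageing libraries, per the file headers, the authors made counts with featureCounts 2.0.1 on exons grouped by gene name (GENCODE vM25), for read pairs and without a strand option, giving 55291 genes. Overlapping and antisense genes, such as Meg3 or Lincpint and their neighbours, can therefore share reads in that set, and the strand setting of the Fus counts is not stated. The deposited CTCF files are SEACR peak lists called per library, with the total and the maximum signal of each peak, scaled by the authors to an unstated target and called at an unstated cut-off. The deposited Hi-C file of the aged cells (other unit: 1 line per valid read pair with the 2 positions) was made with HiC-Pro. No pair occurred more than once in it with the same positions and strands. Because peaks were called per library and with differing lowest signals, numbers of peaks compare libraries only with that limit.

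Counts of the Fus libraries totalled 3389982 to 6406212 (low) and 3747337 to 5642956 (high), with 11813 to 12889 genes detected. Those of the ageing libraries totalled 9882503 to 14947231, with 15359 to 17647 genes detected. Correlations between replicates, across genes on log2(CPM + 1), were 0.938 to 0.955 among Fus low, 0.966 to 0.98 among Fus high and 0.943 to 0.974 in the ageing groups, and 0 pairs of libraries were identical. Reads outside annotated genes made up 15 to 25.7% of the HTSeq total in Fus low and 7.9 to 16.8% in Fus high libraries. Intervals and floors given in the text cover counting error only.

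Each RNA comparison was fitted with edgeR 4.0.16 (quasi-likelihood, robust; filterByExpr; TMM scaling; R 4.3.3), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The 3 groups of the new set shared 1 fit. The difference between the ageing effects of the 2 sets was tested as an interaction over 12 libraries. Unless said otherwise, values are CPM, the counts of each library brought to a common total with TMM scaling, as mean ± SD over libraries. Folds are log2 with the standard error (SE) of the fit where given. A gene at 0 in every library of a group has its fold given as a bound against a floor of 3 counts per library. The p-values of single genes measure differences against the spread between libraries. Since the labels do not tie libraries to animals, that spread may be technical. The tests, the gene lists, the rule for named genes and the first alternatives were written before the data were examined.

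Named genes were Fus and Ctcf, and in each comparison the 12 called genes with the largest fold each way (mean of at least 10 CPM in the higher group; predicted genes counted, not named). Where fewer than 5 passed in a direction, the 5 with the smallest p were named. Of each list discussed, the 4 members with the smallest p were named, and genes chosen otherwise are marked so. The 26 lists covered HSC ageing up, HSC identity, lymphoid priming, megakaryocyte and platelet, myeloid progenitor, G1/S, G2/M, immediate early, interferon response, NF-kB and inflammation, p53 targets, genome architecture, FET and RNA-binding proteins, heat shock and folding, oxidative phosphorylation, autophagy, ribosomal proteins and mitochondrially encoded genes, and the markers of 8 other cell types (B; T and NK; macrophage and monocyte; neutrophil; erythroid; mast and basophil; endothelial; stromal). Lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1, preset correlation 0.01, adjusted over the lists). The test was repeated with the correlation estimated from the data. With the preset correlation the degrees of freedom come from the number of genes, so these p-values can be very small with few libraries. With an estimated correlation they come from the libraries, so a call can be lost without a higher correlation between genes. A second count of members was adjusted over the list alone. Sets of 100 genes with the smallest p each way in the first ageing set, used because fewer than 10 were called, were tested in the other comparisons in the same way.

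The edgeR step was tested on simulated data, with 200 genes changed 2-, 4- or 8-fold in counts modelled on each comparison. The changed genes were drawn from those with a mean above 10 CPM, so recovery of lower genes was not measured. It recovered 71.2, 92.5 and 98.5% of them for Fus high against low (10639 genes), 3, 32.8 and 76.1% for the first ageing set (12821 genes), and 16.7, 68.7 and 91% for the new set (14244 genes). For the knockdown it recovered 18.2, 76.1 and 92.5% against aged (14265 genes) and 13.6, 62.7 and 91% against young (14258 genes). False calls were 1.7, 7.4, 4.1, 3.1 and 4.3% of all calls in that order.

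Peak lists were compared by overlap of at least 1 bp, and numbers of peaks by an exact two-sided permutation test. A gene was taken to carry a peak where a peak lay within 1000 bp of its start in GENCODE vM25 coordinates of the ageing count files (GRCm38, the assembly of mm10). Hi-C pairs at least 10000 bp apart with both ends within 100 kb of a site were sorted into those crossing the site and those on 1 side, in bins of 5000 bp, and compared with sites moved by 200 kb. Percentages carry a 95% exact (Clopper-Pearson) interval; a pair near several sites counts at each of them, so these intervals are narrower than independent pairs would give. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used. Alternatives were DESeq2 size factors, no filter, the DESeq2 1.42.0 Wald test, counts thinned to the smallest library, a replicate block, each library left out, numbers 30, 32 and 36 left out or summed, limma voom with quality weights, limma on the TPM table (pseudocounts 1 and 0.1; TPM of at least 1 in 9 libraries, or no filter), both ageing sets in 1 fit, stricter peak lists, an overlap of 0.5 of both peaks, gene starts at 5000 bp and other Hi-C windows. Others were added after the data were seen and are named as such in the closing observations.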

Results

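CTCF binding and gene expression were compared between HSC sorted as Fus low and Fus high, and between HSC of young and aged mice. Chromatin contacts were examined in HSC of aged mice alone. Knockdown of Fus in aged HSC was added as a further RNA comparison. RNA was measured in 9 Fus low and 9 Fus high libraries, in 3 young and 3 aged libraries of a first set, and in 3 young, 3 aged and 3 aged knockdown libraries of a new set. CTCF peaks came from 2 Fus high, 2 Fus low, 1 young and 1 aged library, and Hi-C pairs from 1 aged library. Total counts ran from 3389982 to 6406212 per Fus library and from 9882503 to 14947231 per ageing library. Low genes were thus measured more finely in the ageing sets, whereas the Fus comparison had more replicates.

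The first comparison asked which genes go with the level of Fus in HSC. Cells of the Fus high libraries carried far more RNA of dividing cells than those of the Fus low libraries. Top2a, the topoisomerase that untangles chromosomes at division, stood at 850.1 ± 152.1 CPM in Fus high and 24.64 ± 15.64 CPM in Fus low (SD, n = 9 each). Genes that mark or maintain HSC were lower in Fus high, with Procr, a surface receptor of dormant HSC, at 12.09 ± 6.385 against 83.08 ± 20.54 CPM. Mpl, the thrombopoietin receptor, stood at 65.62 ± 20.42 against 319 ± 73.62 CPM. Markers of B-lineage cells were higher in the same Fus high libraries, with Cd79a, a subunit of the B cell receptor, at 1000.0 ± 286.1 against 48.49 ± 40.39 CPM. As a list they were not called with an estimated correlation between genes (adjusted p = 0.146), and with the share of reads outside genes as a covariate 1 of the 7 tested was called. Of 10835 genes tested, 2332 rose and 2354 fell in Fus high, and 173 of the 4686 were predicted genes.

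The RNA of Fus itself did not follow the label of the fractions. Fus stood at 38.99 ± 24.34 CPM in the Fus high and 51.68 ± 50.19 CPM in the Fus low libraries (n = 9 each; chromosome 7, 127967457 to 127985701, mm10), a log2 fold of -0.41 (SE 0.40, adjusted p = 0.441). The sign rested on 1 Fus low library, number 36-6, without which the log2 fold was 0.137. This fold was 0.362 without number 36, -0.973 without number 30 and -0.794 with limma on the authors' TPM table, and not called in any of them. Ctcf, on chromosome 8 from 105636568 to 105682922, stood at 168.5 ± 41.03 against 100.6 ± 31.33 CPM and rose by 0.75 on the log2 scale (SE 0.18, adjusted p = 0.00164), with 5 of 9 Fus high libraries above every Fus low library. The call of Ctcf held in every alternative run on the counts (adjusted p from 8.55e-05 to 0.04504), with log2 folds from 0.655 without library 36-6 to 1.484 with the share of reads outside genes as a covariate. It was lost with limma on the authors' TPM table, where the fold was 0.21 (adjusted p = 0.404, and up to 0.4516 with another pseudocount or filter) and the median gene stood at -0.425.

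**Figure D1:**
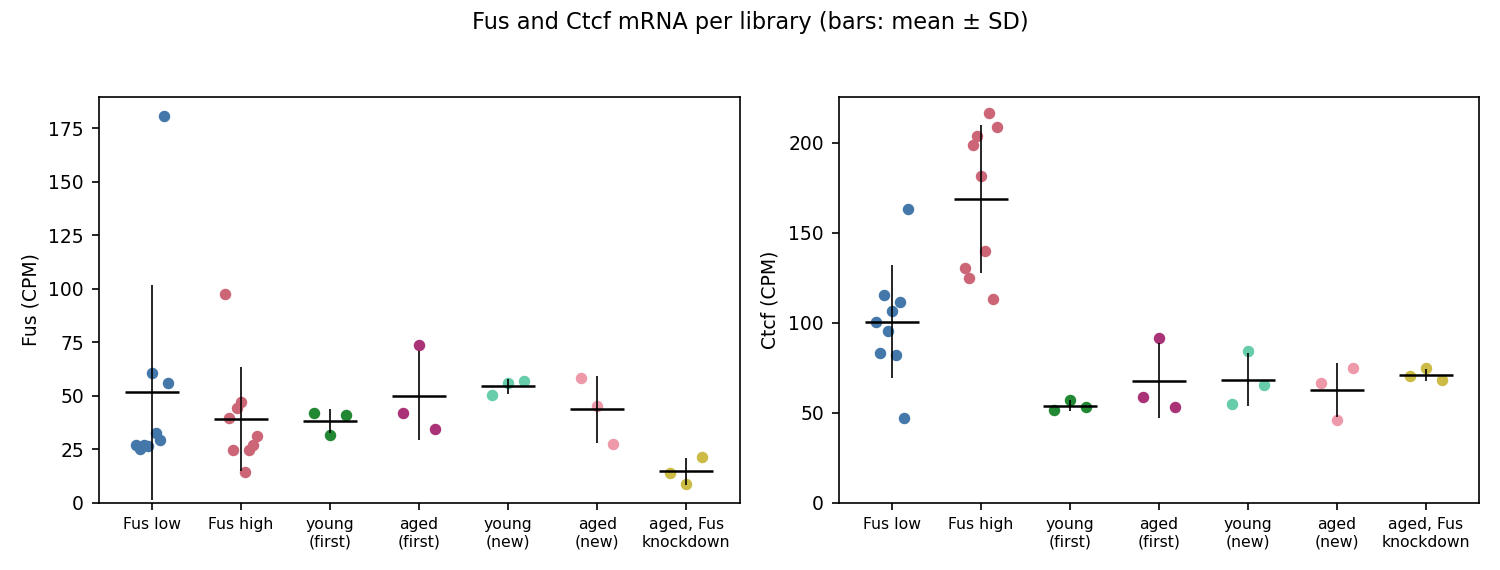
CPM of Fus and Ctcf in each RNA library, with the mean and SD of each group. Shown are the 9 Fus low and 9 Fus high libraries and the young, aged and knockdown libraries of the ageing sets. The Fus comparison and each ageing set were scaled separately. The Fus values of the Fus low and Fus high groups overlap, whereas the mean of Ctcf is 168.5 CPM in Fus high and 100.6 CPM in Fus low.

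The 12 called genes with the largest rise in Fus high were near 0 in Fus low. Bcat1, an enzyme of branched-chain amino acid breakdown (chromosome 6, 144993835 to 145076184), stood at 26.56 ± 14.63 against 0.0209 CPM, a log2 fold of 9.26 (SE 0.63, adjusted p = 2.746e-11). Prss50, a serine protease gene on chromosome 9 (110857967 to 110864629), followed at 16.24 ± 10.11 against 0.035 CPM (log2 fold 8.04, SE 0.69, adjusted p = 1.345e-09). Hist1h2ai (7.79), Hist1h2ak (6.89) and Hist1h1b (6.55) encode histones, whose genes have near-identical copies, so the share of each copy is uncertain. Eme1 (7.19), a subunit of a DNA repair nuclease, and Neil3 (6.61), a DNA glycosylase, rose with Kif18b (6.72), a mitotic kinesin, and Bub1 (6.37), a kinase of the mitotic checkpoint. The last 3 were Mxd3 (7.02), a partner of the transcription factor Max, Efcab11 (6.50) and Gfra2 (6.37), a receptor of the ligand neurturin.

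The 12 with the largest fall were led by Meg3, an imprinted long noncoding RNA on chromosome 12 (109541001 to 109571726), which fell by 5.79 (SE 0.81, adjusted p = 2.781e-06) from 14.29 ± 8.4 to 0.24 CPM. Then came Unc45b (-5.19), a chaperone of myosin, Thnsl2 (-4.19), the noncoding RNA Lincpint (-4.06), Igdcc4 (-3.77) and Pygm (-3.71), the muscle glycogen phosphorylase. Tcp11l2 (-3.60), Cd7 (-3.58), Batf2 (-3.54), Kazald1 (-3.54), Clec1a (-3.53) and Tinagl1 (-3.45) completed them. Meg3 and Lincpint overlap other transcripts, so part of their counts may belong to those. With the covariate of reads outside genes, the calls of Thnsl2, Lincpint, Cd7, Batf2, Kazald1 and Clec1a were lost.

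Genes of the cell cycle rose together in Fus high. All 22 tested G2/M genes rose over all genes tested and adjusted over the list alone, with a median log2 fold of 4.69 (adjusted p = 3.57e-22). Cdk1 (4.53), the kinase that drives entry into mitosis, rose with Top2a (5.11) and the spindle genes Nusap1 (4.86) and Kif11 (5.47). Of 25 G1/S genes, 22 rose and 2 fell (23 and 2 adjusted over the list alone; median 2.51, adjusted p = 3.93e-23). They included Mcm7 (2.01) and Mcm5 (2.66) of the replicative helicase, Pcna (2.52), the sliding clamp, and Rrm1 (3.45), a subunit of ribonucleotide reductase. Both calls held with an estimated correlation (adjusted p = 0.00941 and 0.00534). Of 24 genome architecture genes 17 rose and 1 fell, the same counts adjusted over the list alone (median 1.07, adjusted p = 2.84e-09; 0.00913 with an estimated correlation). Smc2 (3.22), Ncapd2 (3.21) and Smc4 (2.34) of condensin, which compacts chromosomes, led this group with Lbr (1.50), the lamin B receptor. With the covariate 22 of 22 G2/M, 19 of 25 G1/S and 16 of 24 genome architecture genes were called higher.

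Genes of energy supply and protein handling were also higher in Fus high. Of 26 oxidative phosphorylation genes 25 rose (26 adjusted over the list alone), with a median of 0.92 (adjusted p = 4.01e-15; 0.00913 with an estimated correlation). Cox5a (1.46), Cox7a2 (1.23) and Cox5b (1.10) encode subunits of cytochrome c oxidase, and Cycs (2.14) cytochrome c. Heat shock and folding genes rose in 12 of 15 (12 adjusted over the list alone; median 0.72, adjusted p = 9.03e-06; adjusted p = 0.0958 with an estimated correlation). Chaperones of the cytosol, Hsp90aa1, Hspa8 (1.34) and Cct2 (0.81), rose with Hspe1 (1.49) of the mitochondrion. The medians of the next 2 lists were just under 0 on the authors' TPM table, though above its median gene (-0.425). Ribosomal protein genes rose in 62 of 76 (63 adjusted over the list alone; median 0.51, adjusted p = 8.28e-09; adjusted p = 0.32 with an estimated correlation), with a median of -0.05 on TPM. FET and RNA-binding protein genes, a list that holds Fus itself, rose in 12 of 21 and fell in 1, the same counts adjusted over the list alone. Their median was 0.64 (adjusted p = 0.017, and 0.146 with an estimated correlation), and -0.04 on TPM. Named members were Rpl4 (0.87), Rpl41 (1.20), Rpl15 (0.66) and Rpl14 (0.77), and Hnrnpu (1.06), Ddx17 (-0.94), Ilf3 (0.66) and Nono (0.73). With the covariate 22 of 76 ribosomal protein genes were called higher, 17 of 26 oxidative phosphorylation genes, 8 of 15 heat shock and folding genes and 8 of 21 FET and RNA-binding protein genes, and the 4 lists stayed called. Their medians were then 0.423, 0.713, 0.662 and 0.477 in that order.

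Genes of HSC identity fell together in Fus high. Of 23 tested, 18 fell and 1 rose (20 and 1 adjusted over the list alone; median -1.46, adjusted p = 2.34e-12; 0.00534 with an estimated correlation). Mpl (-2.28) and Procr (-2.78) fell with Kit (-1.37), the stem cell factor receptor, and Meis1 (-1.51), a homeobox factor of HSC. NF-kB and inflammation genes fell in 9 of 12 (9 adjusted over the list alone; median -1.01, adjusted p = 9.03e-06; 0.0249 with an estimated correlation). The chemokines Ccl3 (-3.02) and Ccl4 (-2.75), the inhibitor Nfkbia (-1.14) and Nfkb2 (-1.09) were among them. Interferon response genes fell in 18 of 25 and 1 rose, the same counts adjusted over the list alone (median -1.18, adjusted p = 1.2e-05; adjusted p = 0.0545 with an estimated correlation). Oasl2 (-1.77) and Oas2 belong to the antiviral oligoadenylate synthetase family and fell with Rtp4 (-1.27) and Stat1 (-1.01), the signal transducer of interferon. Immediate early genes fell in 9 of 12 (9 adjusted over the list alone; median -0.90, adjusted p = 0.00781; adjusted p = 0.16 with an estimated correlation), including Egr1 (-3.02), Ier3 (-1.93), Junb (-1.83) and Ier2 (-1.04). Autophagy genes fell in 6 of 16 (6 adjusted over the list alone; median -0.32, adjusted p = 0.00691; 0.0234 with an estimated correlation). Ulk1 (-1.47), Gabarapl1 (-1.32) and Map1lc3b (-0.75), parts of the autophagosome machinery, and the cargo receptor Sqstm1 fell. With the covariate 11 of 23 HSC identity, 9 of 25 interferon response, 8 of 12 NF-kB and inflammation, 6 of 12 immediate early and 5 of 16 autophagy genes were called lower, and the 5 lists stayed called. Their medians were then -1.274, -1.053, -1.408, -1.784 and -0.367 in that order.

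Smaller groups moved less evenly. Genes reported to rise in aged HSC fell in 6 of 16 and rose in 1 (the same adjusted over the list alone; median -1.18, adjusted p = 0.0417; adjusted p = 0.209 with an estimated correlation). Sult1a1 (-3.18), Tgm2 (-2.68), Alcam (-1.20) and Enpp5 (-1.38) fell, and the list's call was lost without Fus high 30-3 and Fus low 30-4 (adjusted p = 0.0805) and with the covariate (0.148). Megakaryocyte and platelet genes fell in 5 of 18 and rose in 1 (the same adjusted over the list alone; median -0.44, adjusted p = 0.0417; adjusted p = 0.146 with an estimated correlation). Nfe2 (-1.14), a factor of platelet formation, Plek (-1.45) and Selp (-1.31) fell, and the list's call was lost without Fus low 36-6 (0.0579). Lymphoid priming genes went both ways, 8 up and 7 down of 18 (8 and 8 adjusted over the list alone; adjusted p = 0.662). Dntt (1.95) and Rag2 (2.51), which act on antigen receptor genes, rose, and Flt3 (-0.95) and Sox4 (-1.61) fell. Myeloid progenitor genes had 1 up and 4 down of 16, the same adjusted over the list alone, and were not called as a list (adjusted p = 0.45); their median of -0.19 was 0.38 on the TPM table, against the shift of its median gene. Csf3r (-1.60), Csf2rb (-1.52), Spi1 (-0.70) and Gfi1 (-1.31) fell. Targets of p53 had 3 up and 3 down of 14, the same adjusted over the list alone (adjusted p = 0.387). Among them Cdkn1a (2.03), an inhibitor of the cell cycle, and Bax rose and Sesn1 (-1.09) and Bbc3 (-2.07) fell. With the covariate 1 of 16 genes that rise in aged HSC, 3 of 18 megakaryocyte and platelet, 3 of 16 myeloid progenitor and 2 of 14 p53 target genes were called lower and none of them higher, and 5 lymphoid priming genes were higher and 4 lower.

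Markers of other cell types also differed. All 7 tested B cell markers rose (7 adjusted over the list alone; median 3.46, adjusted p = 0.000278; adjusted p = 0.146 with an estimated correlation), in the libraries in which the cell-cycle genes rose. Cd79b (2.02), Cd79a (4.36), Cd19 (3.46) and Vpreb3 (3.57) belong to B cell and pre-B cell receptor complexes. With the covariate, 1 of these 7 was called, with a median of 2.09. Macrophage and monocyte markers fell in 3 of 5 (4 adjusted over the list alone; median -2.49, adjusted p = 0.0389; adjusted p = 0.19 with an estimated correlation). These were the complement genes C1qa (-2.49), C1qb (-3.41) and C1qc (-2.54), and the list's call was lost with the covariate (0.0788). Erythroid markers had 4 of 7 higher (4 adjusted over the list alone; median 2.31), namely Klf1, Car1 (4.20), Ermap (2.90) and Rhag (2.31). They were not called as a list (adjusted p = 0.0527; adjusted p = 0.297 with an estimated correlation). With the covariate the list passed (0.0331) but 0 of its 7 members did. Endothelial markers had 2 of 3 lower, Pecam1 (-0.76) and Emcn (-1.41) (adjusted p = 0.187), and neutrophil markers had 0 of 4 called (adjusted p = 0.662). Mitochondrially encoded genes, T and NK, mast and basophil and stromal markers had fewer than 3 tested members.

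**Figure D2:**
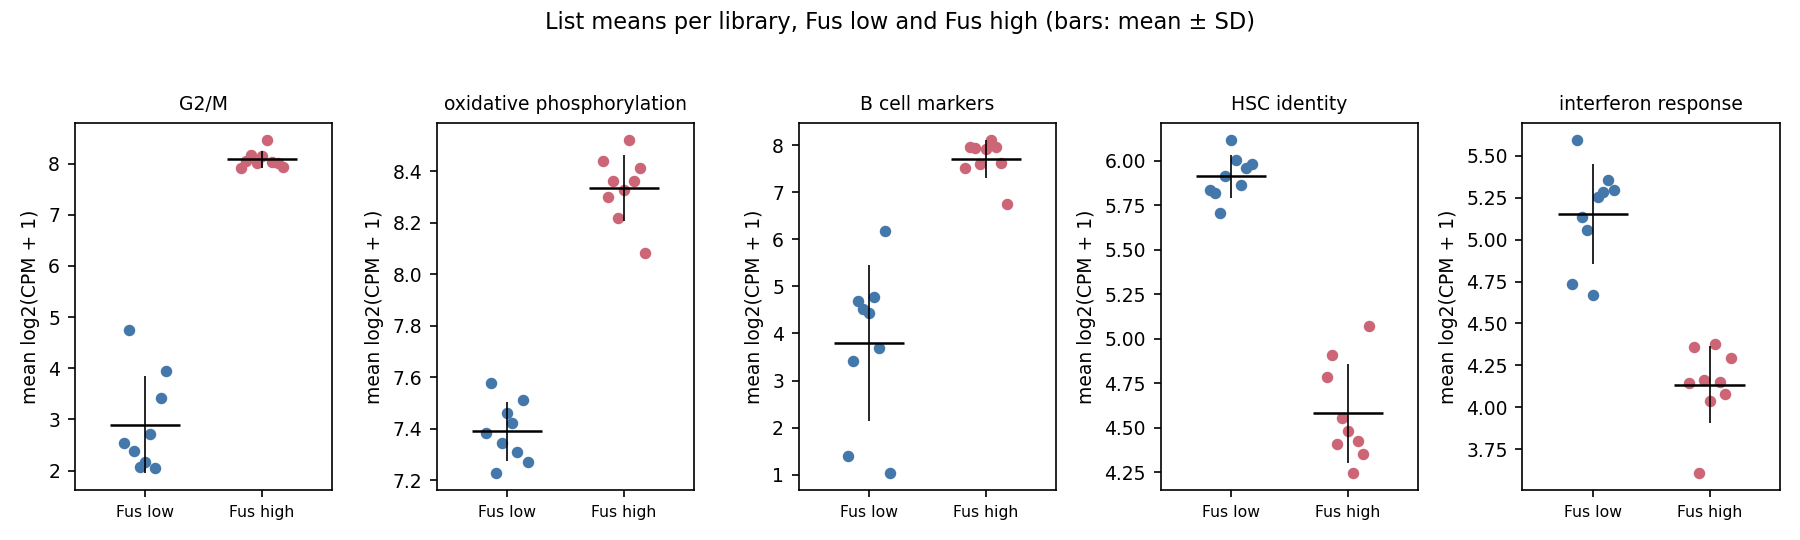
Mean log2(CPM + 1) of 5 gene lists in each of the 9 Fus low and 9 Fus high RNA libraries, with group means and SD. The means of G2/M, oxidative phosphorylation and B cell markers are higher and those of HSC identity and interferon response lower in Fus high.

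The split of 2332 up and 2354 down holds under TMM scaling, at which the median gene stood at -0.069. On the TPM table the median gene stood at -0.425, 5429 genes were called, and 20.6% of them were up against 49.8% of the counts' calls, so changes are relative to those medians. Of all genes tested, 1326 (12.2%) separated all Fus high from all Fus low libraries. With the covariate, which nearly follows the label, 1927 genes were called, of which 1785 were shared with the 4686.

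The second comparison asked what changes with age, in the first set. Nupr1, a stress-response regulator of transcription (chromosome 7, 126623249 to 126630861), stood at 275.8 ± 32.25 CPM in aged and 52.66 ± 8.276 CPM in young HSC (SD, n = 3 each), a rise of 2.39 on the log2 scale (SE 0.19, adjusted p = 0.0328). Selp, which encodes the adhesion protein P-selectin (chromosome 1, 164115264 to 164150026), stood at 161 ± 43.9 against 10.35 ± 4.696 CPM, a rise of 3.96 (SE 0.39, adjusted p = 0.0459). Ddx3y (-10.19, adjusted p = 0.0328; 47.05 ± 19.62 CPM in young) and Eif2s3y, both on the Y chromosome, fell, the latter from 57.6 ± 16.16 to 0 CPM, which is at least 213.9-fold lower (adjusted p = 0.04005). Genes reported to rise in aged HSC were higher as a group in the aged libraries, and so were G1/S genes of the cell cycle.

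These 4 were the only genes edgeR called of 13674 tested, while 1435 had an unadjusted p under 0.05, DESeq2 called 627, and 2476 (18.1%) separated all aged from all young libraries where chance gives 10%. Not one of the 4 calls held with any 1 of the 6 libraries left out (adjusted p between 0.08674 and 0.2069). The log2 folds in those fits were 2.28 to 2.512 for Nupr1, 3.719 to 4.385 for Selp and -12.135 to -9.656 for Ddx3y. Higher without passing were Plscr2 (log2 fold 2.72, adjusted p = 0.0743), Tyms (2.09, 0.0977) and Hsp90aa1 (0.95, 0.101). Lower without passing were Prkcd (-1.36, 0.0917), and the Y-linked Kdm5d (at least 75.08-fold, 0.123) and Uty (at least 70.7-fold, 0.127). Xist, the RNA that silences an X chromosome in females, was chosen outside the rule for named genes. It stood at 125.6 ± 28.5 against 0.985 CPM (log2 fold 6.93, adjusted p = 0.123). In both sets the aged libraries, those of the knockdown included, had Xist and little Y-linked RNA, and the young libraries the reverse. Age and sex therefore cannot be told apart for genes on other chromosomes. Fus (50.03 ± 20.82 against 38.18 ± 5.584 CPM, log2 fold 0.39, SE 0.35, adjusted p = 0.81) and Ctcf (67.78 against 54 CPM, 0.33, adjusted p = 0.789) did not pass.

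Of 29 genes on the list of those that rise in aged HSC, all 29 had a positive fold, with a median of 1.67. Adjusted over all genes 2 rose and adjusted over the list alone 22 did (list adjusted p = 8.19e-42; 0.00225 with an estimated correlation). Besides Nupr1 and Selp, its named members were Mt1 (3.18), a metallothionein, and Vwf (2.03), the von Willebrand factor. The list was drawn up from general knowledge of HSC ageing and not from these libraries. For G1/S genes 0 of 25 were called over all genes and 15 rose and 1 fell adjusted over the list alone (median 1.27, adjusted p = 1.18e-16; 0.0323 with an estimated correlation). Cdk6 (1.69), a kinase of G1, Mcm5 (2.15), Mcm7 and Tyms, thymidylate synthase, had the smallest p. Both calls held with each library left out.

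The other list calls of the first set were lost with an estimated correlation, and none of these lists had a member called over all genes save Selp among the megakaryocyte and platelet genes. G2/M genes had 5 of 22 higher adjusted over the list alone (median 2.71, adjusted p = 2.68e-12; adjusted p = 0.275 with an estimated correlation). Top2a had a log2 fold of 4.27, Mki67 of 3.33 and Cdk1 of 1.95, and Bub1 was at 0 in young and at least 36.78-fold higher in aged. Interferon response genes had 3 of 25 higher adjusted over the list alone (median 0.71, adjusted p = 4.6e-05; adjusted p = 0.275 with an estimated correlation), among them Rtp4 (1.47) and the GTPases Iigp1 (1.58) and Igtp (1.69). Megakaryocyte and platelet genes had 5 higher and 1 lower of 20 adjusted over the list alone (median 0.56, adjusted p = 0.000441; adjusted p = 0.1 with an estimated correlation), among them Gata1, at 35.95 ± 38.36 CPM in aged and 0 in young. Oxidative phosphorylation had 2 of 26 higher adjusted over the list alone (median 0.22, adjusted p = 0.00266; adjusted p = 0.367 with an estimated correlation) and lost its call without Young replicate 3 (0.0725). Genome architecture had 1 of 24 (median 0.31, adjusted p = 0.00713; adjusted p = 0.275 with an estimated correlation) and lost it without Aged replicate 2 (0.112). Heat shock and folding (5 of 16 higher adjusted over the list alone, median 0.13), HSC identity (2 of 24 lower, median -0.07, with Mpl at -0.73) and NF-kB and inflammation (0 of 12, median -0.54) each had an adjusted p of 0.0384, and of 0.367, 0.275 and 0.275 with an estimated correlation. Heat shock and folding lost its call without any 1 library but Aged replicate 1. HSC identity lost it without Aged replicate 2 or 3 or Young replicate 2, and NF-kB and inflammation without Aged replicate 2 or Young replicate 2 or 3.

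Not called in the first set were lymphoid priming (adjusted p = 0.859), myeloid progenitor (0.859), immediate early (0.84), p53 targets (0.398) and FET and RNA-binding proteins (0.0865). Nor were autophagy (0.753), ribosomal proteins (0.156) and mitochondrially encoded genes (0.0654). Among other cell types the B cell (0.987), macrophage (0.842), neutrophil (0.356), erythroid (0.0654) and endothelial (0.563) markers were not called. The T and NK, mast and stromal markers had fewer than 3 tested members. Several of these passed with 1 library left out. B cell markers did without Aged replicate 1 (1.84e-19) or Young replicate 1 or 3 (0.0317 and 0.0455), and erythroid markers without any 1 library but Aged replicate 2 (from 4.14e-09 to 0.0233). Neutrophil markers passed without Young replicate 1 (0.000856), ribosomal proteins without Aged replicate 2 (0.00501) or Young replicate 3 (0.0486) and mitochondrially encoded genes without Aged replicate 3 (0.0101). Lymphoid priming passed, with the direction turned, without Aged replicate 1 (0.0128). The mean log2(CPM + 1) of B cell markers ran from 2.04 to 6.20 in young and from 2.21 to 6.89 in aged libraries, and that of neutrophil markers was 10.4 in Young replicate 3.

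In the new set, haemoglobin RNA was higher in the aged than in the young libraries. Hbb-bs, an adult beta-globin, stood at 2790 ± 1608 CPM in aged and 6.034 ± 2.117 CPM in young libraries (SD, n = 3 each; adjusted p = 0.00318), and Hba-a1, Hba-a2 and Hbb-bt rose by 8.18, 8.75 and 7.06 on the log2 scale (adjusted p = 0.0199, 0.0286 and 0.00415). Hba-a1 and Hba-a2 are near-identical copies, so their shares are uncertain. Slc15a2, a peptide transporter, rose from 0 to 29.66 ± 5.781 CPM, at least 138.7-fold (adjusted p = 0.00318). Xist rose by 8.45 to 537.9 ± 179.1 CPM (adjusted p = 0.00319), and the Y-linked Eif2s3y fell from 64.6 ± 20.16 to 0 CPM, at least 257.4-fold (adjusted p = 0.00319).

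These 7 were all the genes called by edgeR of 15051 tested (6 up and 1 down). An unadjusted p under 0.05 was found for 843, DESeq2 called 132, and 1535 (10.2%) separated the groups where chance gives 10%. Slc15a2, Hbb-bs, Xist and Eif2s3y kept their calls with each of the 6 libraries left out, whereas 4 or 5 genes were called without newAged replicate 2 or any 1 young library. Hba-a1 and Hba-a2 lost theirs without newAged replicate 2 or any 1 young library (adjusted p from 0.06548 to 0.3284), and Hbb-bt without newYoung replicate 2 or 3 (0.0675 and 0.06313). Their log2 folds in those fits were 7.788 to 8.47, 8.45 to 9.147 and 6.827 to 6.945. Lower but not past the threshold were Kdm5d (at least 109.6-fold, adjusted p = 0.0526), Rps4l (at least 63.83-fold, 0.069), Uty (at least 50.33-fold, 0.209) and Hnf4a (at least 51.72-fold, 0.261). Fus (43.79 ± 15.68 against 54.45 ± 3.537 CPM, adjusted p = 0.9998) and Ctcf (62.56 against 68.19 CPM, -0.12, adjusted p = 0.9998) did not pass.

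Erythroid markers were higher in the aged libraries of the new set in all 12 members tested (4 called over all genes, 5 adjusted over the list alone; median 4.80, adjusted p = 2.45e-38; 0.00305 with an estimated correlation). The list of genes that rise in aged HSC had 0 of 29 called over all genes, 1 adjusted over the list alone and 20 positive (median 0.37, adjusted p = 0.000712; adjusted p = 0.345 with an estimated correlation). Ribosomal proteins had 70 of 77 positive (median 0.20, adjusted p = 5.63e-08; adjusted p = 0.679 with an estimated correlation; lost without newAged replicate 1, 0.0524), and G2/M genes had 1 of 22 positive (median -0.38, adjusted p = 0.000153; adjusted p = 0.679 with an estimated correlation; lost without newYoung replicate 2, 0.161). Heat shock and folding had a median of 0.23 (adjusted p = 0.0442; adjusted p = 0.519 with an estimated correlation) and lost its call without newAged replicate 2 or 3 or newYoung replicate 1 or 2 (0.063 to 0.316). No other list passed: G1/S genes had a median of -0.01 (adjusted p = 0.657), and HSC identity (0.498), megakaryocyte and platelet (0.152), interferon response (0.916) and oxidative phosphorylation genes (0.654) did not differ from other genes by the test. With 1 library left out, genome architecture passed without newAged replicate 1 (0.0466 against 0.116) and mitochondrially encoded genes without newYoung replicate 3 (0.0432 against 0.557).

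The difference between the ageing effects of the 2 sets was tested gene by gene. The test called 4 of 15723 genes, a count for which chance cannot be excluded, since other splits of the libraries gave up to 9. Txnip, a regulator of glucose uptake, stood at 1869 CPM in young and 1250 CPM in aged libraries of the first set and at 615.3 and 1044 CPM in the new set (difference 1.34, SE 0.16, adjusted p = 0.02796). Mfsd2b (adjusted p = 0.02796), Bub1 (0.03292) and Tedc1 (0.04007) were at 0 in all young libraries of the first set and at 61.56, 20.41 and 24.93 CPM in young libraries of the new set. The difference also passed for the list of genes that rise in aged HSC (median -1.31, adjusted p = 6.92e-11; 0.0123 with an estimated correlation), for megakaryocyte and platelet genes (-0.59, 0.00034; 0.0202 with an estimated correlation) and for G1/S genes (-1.27, 5.19e-15; 0.00819 with an estimated correlation), all less positive in the new set. A further 6 lists passed only with the preset correlation: G2/M (-3.11, 3.05e-18; adjusted p = 0.0924 with an estimated correlation), genome architecture (-0.52, 6.31e-05; 0.0906), interferon response (-0.75, 0.00167; 0.384), ribosomal proteins (0.08, 0.0322; 0.824), neutrophil markers (7.96, 0.0322; 0.433) and erythroid markers (0.000244; 0.0629), whose test pointed up at a median of -0.25. With 1 of the 12 libraries left out the count was 0 without newAged replicate 2, newYoung replicate 1 or 2 or Aged replicate 2 or 3, and 1 without newYoung replicate 3. It was 7 without newAged replicate 3, 9 without Young replicate 1 or 3 or Aged replicate 1, and 24 without Young replicate 2.

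**Figure D3:**
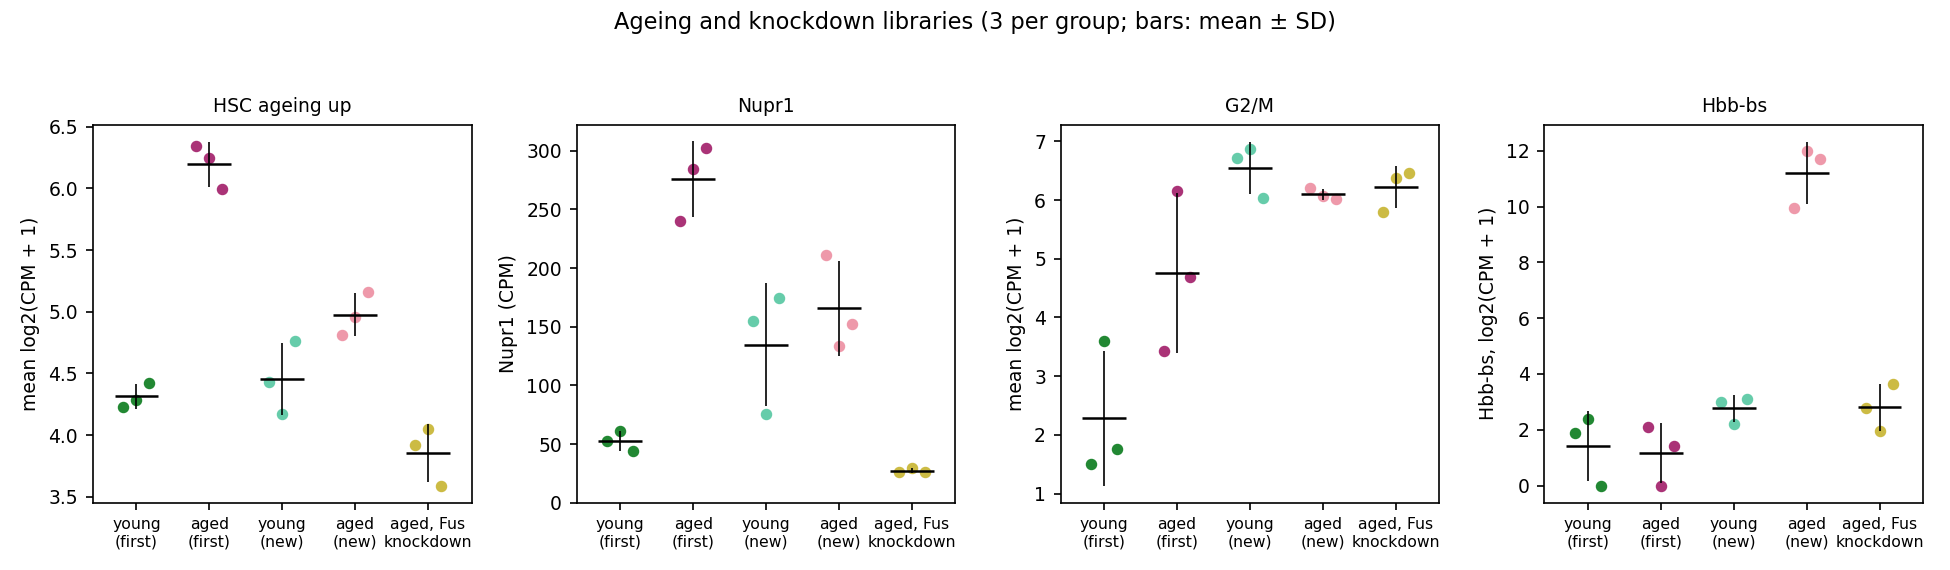
Values of each ageing and knockdown RNA library, as the mean log2(CPM + 1) of genes that rise in aged HSC and of G2/M genes, the CPM of Nupr1 and the log2(CPM + 1) of Hbb-bs, with group means and SD. Nupr1 is higher in the aged libraries of the first set than in the young ones and lowest in the knockdown libraries, and Hbb-bs is high in the aged libraries of the new set.

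The knockdown comparison asked which genes differ between aged HSC with and without knockdown of Fus. The labels do not say whether both were handled alike, so a difference cannot be ascribed to Fus alone. Fus stood at 14.66 ± 6.275 CPM in the knockdown and 43.79 ± 15.68 CPM in the aged libraries (SD, n = 3 each), with each knockdown library below each aged one. Its log2 fold of -1.58 (SE 0.38) did not pass over all genes with edgeR (adjusted p = 0.35) and did with DESeq2 (adjusted p = 0.00666). Genes reported to rise in aged HSC were lower in the knockdown. Nupr1 fell by 2.60 on the log2 scale, from 165.7 ± 40.24 to 27.3 ± 2.039 CPM (adjusted p = 0.0381), and Tgm2, a transglutaminase on chromosome 2 (158116402 to 158146436), by 1.80, from 160.2 ± 6.051 to 46.15 ± 11.11 CPM (adjusted p = 0.0282). Neither was called in aged against young of this set, where young libraries held 134.7 ± 52.28 CPM of Nupr1 and 128.7 ± 13.1 CPM of Tgm2. Haemoglobin RNA was also lower, as Hbb-bs fell by 8.69 to 6.803 ± 4.408 CPM (adjusted p = 0.00719), Hba-a2 by 7.74 and Hba-a1 by 6.99 (both adjusted p = 0.0466). Gstm2, a glutathione transferase, fell by 4.01 from 50.59 ± 18.62 to 3.135 CPM (adjusted p = 0.0466), and Prss50 rose from 0 to 45.02 ± 10.67 CPM, at least 179.4-fold (adjusted p = 0.0381).

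With 1 predicted gene that fell these were the 8 calls of 15051 genes (1 up and 7 down). An unadjusted p under 0.05 was found for 1414, DESeq2 called 319, and 2194 (14.6%) separated the groups where chance gives 10%. The count fell to 0 without knockdown replicate 2, to 1 without knockdown replicate 1 or newAged replicate 2 or 3, and to 3 without knockdown replicate 3, and no library could be left out without loss of the calls of Nupr1 and Gstm2 (adjusted p up to 0.2648 and 0.3172). Their log2 folds in those fits were -2.721 to -2.371 and -4.318 to -3.624. Hbb-bs lost its call without knockdown replicate 1 or 2 (0.07567 and 0.05088), Hba-a1 and Hba-a2 without knockdown replicate 1 or 2 or newAged replicate 2 or 3 (0.06575 to 0.2324 and to 0.2331), Tgm2 without knockdown replicate 2 or 3 or newAged replicate 2 or 3, and Prss50 without any 1 library but newAged replicate 1. Higher but not past the threshold were Gfi1b (1.20, adjusted p = 0.0993), a factor of erythroid and platelet cells, Ppia (0.90), Tmem14c (1.13) and Casp3 (1.14). Ctcf (log2 fold 0.18, adjusted p = 0.911) and Xist (-0.08, adjusted p = 0.994), the latter chosen outside the rule for named genes, did not pass.

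Of the 29 genes that rise in aged HSC, 2 fell in the knockdown over all genes and 11 adjusted over the list alone (median -0.996, 3 positive; adjusted p = 6.42e-16; 0.015 with an estimated correlation). Nupr1, Tgm2, Selp (-1.61) and Sult1a1 had the smallest p. Of 21 megakaryocyte and platelet genes 0 were called over all genes and 6 were lower adjusted over the list alone (median -0.41, adjusted p = 0.000189; 0.0415 with an estimated correlation). Selp, Itga2b (-1.49), the platelet integrin, Cd9 (-0.96) and Vwf (-0.90) had the smallest p. Both list calls held with each library left out. HSC identity genes had 1 higher and 3 lower adjusted over the list alone (median -0.34, adjusted p = 0.0388; adjusted p = 0.274 with an estimated correlation), with Gata2 at -0.79, Lmo2 at -0.58 and Meis1 at -0.71. The call was lost without knockdown replicate 2 or 3 or newAged replicate 1 or 3 (0.0608 to 0.189), and with a replicate block (0.0502).

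Other list calls of the knockdown did not hold with an estimated correlation. Erythroid markers had 3 of 12 lower over all genes, and 5 lower and 2 higher adjusted over the list alone (median -1.30, adjusted p = 3.09e-05; adjusted p = 0.272 with an estimated correlation). Oxidative phosphorylation genes had 25 of 26 positive (median 0.28, adjusted p = 0.000249; adjusted p = 0.312 with an estimated correlation) and G1/S genes 19 of 25 (median 0.49, adjusted p = 0.00125; adjusted p = 0.312 with an estimated correlation; lost without knockdown replicate 3, 0.0557). Ribosomal proteins had a median of 0.08 (adjusted p = 0.0388; adjusted p = 0.822 with an estimated correlation) and lost their call without knockdown replicate 1 (0.0675) or newAged replicate 3 (0.186, with the direction turned). Not called were, among others, G2/M (median 0.15, 0.517), interferon response (0.531), myeloid progenitor (1.24, 0.274), neutrophil (4.00, 0.394) and mast and basophil genes (2.00, 0.181). With 1 library left out, myeloid progenitor genes passed without knockdown replicate 1 or 2 (0.00307 and 0.00901), and so did neutrophil genes (0.0349 and 0.0103). G2/M (0.0199) and mast and basophil genes (0.0071) passed without knockdown replicate 1. Immediate early genes (0.0558) passed without knockdown replicate 1 or 3 or newAged replicate 1 (0.0163, 0.0479 and 0.0466). NF-kB and inflammation genes (0.0558) did without knockdown replicate 2 or newAged replicate 2 (0.00901 and 0.0223), and heat shock and folding genes (0.0592) without knockdown replicate 1 or newAged replicate 3 (0.0071 and 0.00977). Knockdown replicate 3 carried Elane (1776 CPM), Mpo (944.3 CPM) and S100a8 (457.4 CPM), transcripts of granulocyte precursors and granulocytes chosen here after their values were seen. Elane was at most 0.0875 CPM in the other 8 libraries of the set.

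Against young HSC of the new set, the knockdown libraries of aged HSC differed in 12 genes (5 up and 7 down; 1181 at an unadjusted p under 0.05, 280 by DESeq2, and 2750, or 18.3%, separated where chance gives 10%). Prss50 (at least 210.5-fold), Slc15a2 (at least 140.3-fold), Xist (8.37), Hbb-bt (4.41) and Gdf3 (1.77), a growth factor of the TGF-beta family, were higher. Eif2s3y (-10.75), Kdm5d (at least 109-fold), Gstm2 (-4.44), Nupr1 (-2.30; 27.3 against 134.7 CPM), Gstt1 (-2.05), Tgm2 (-1.48) and Cd9 (-1.47) were lower. With 1 library left out the count was 2 to 5, and only Slc15a2 and Xist kept their calls each time. The folds behind the lost calls kept their direction, with Gdf3 at 1.64 to 1.931, Gstt1 at -2.117 to -1.946 and Cd9 at -1.629 to -1.289. Fus stood at 14.66 ± 6.275 against 54.45 ± 3.537 CPM (log2 fold -1.89, adjusted p = 0.182), and Ctcf at a log2 fold of 0.06 (adjusted p = 0.998).

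Megakaryocyte and platelet genes were lower in the knockdown than in young HSC (median -0.69, 1 lower over all genes and 7 adjusted over the list alone; adjusted p = 3.34e-09; 0.011 with an estimated correlation). Genes that rise in aged HSC were lower as well (median -0.62, 2 lower over all genes, 8 lower and 1 higher adjusted over the list alone; adjusted p = 5.6e-07; 0.0489 with an estimated correlation), and so were HSC identity genes (median -0.42, adjusted p = 0.000508; 0.0489 with an estimated correlation). Heat shock and folding genes were higher (median 0.40, 0 called over all genes and 4 adjusted over the list alone; adjusted p = 1.04e-05; 0.0489 with an estimated correlation). Erythroid markers were also higher (median 3.09, 1 over all genes and 6 adjusted over the list alone; adjusted p = 4.97e-13; 0.0374 with an estimated correlation). These 5 calls held with each library left out. A further 6 lists passed only with the preset correlation: G1/S (0.26; adjusted p = 0.302 with an estimated correlation), G2/M (-0.29; 0.532), p53 targets (0.71; 0.111), oxidative phosphorylation (0.31; 0.175), ribosomal proteins (0.29; 0.314) and mast and basophil markers (2.70; 0.181). Of these, G1/S lost its call without knockdown replicate 3 (0.118), and G2/M without knockdown replicate 1 (0.291) or newYoung replicate 1 or 2 (0.0828 and 0.304). Mast and basophil markers lost theirs without knockdown replicate 2 (0.229) or newYoung replicate 1 or 3 (0.0989 and 0.0819). Myeloid progenitor (0.341) and neutrophil genes (0.202), not called with all libraries, passed without knockdown replicate 1 or 2 (0.00342 to 0.0172). Immediate early (0.0755) and mitochondrially encoded genes (0.053) passed without knockdown replicate 1 or 3 or newYoung replicate 3 (0.00147 to 0.0436).

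The genes that differed most with age in the first set were followed in the other comparisons. The 100 with the smallest p among those higher in aged were higher in Fus high than Fus low (72 tested, 49 up and 6 down, median 1.38, adjusted p = 2.75e-18; 0.000119 with an estimated correlation), and the 100 lower in aged were lower (87 tested, 0 up and 63 down, median -0.78, adjusted p = 1.07e-15; 1.49e-05 with an estimated correlation). Without the sex-linked genes 86 of the lower set were tested (adjusted p = 2.73e-16). Each set was refilled to 100 when the members of the cell-cycle lists were also left out. Of the higher set 70 were then tested, 48 up and 6 down (median 1.38, adjusted p = 6.55e-18). Cell-cycle genes outside those lists could stay in the sets, so whether the cell cycle links the comparisons cannot be told. In the knockdown against aged HSC the higher set had a median of 0.21 and a mean of -0.141 (adjusted p = 0.43) and the lower set a median of -0.27 (1.25e-05; adjusted p = 0.118 with an estimated correlation). In the new ageing set the medians were 0.14 (adjusted p = 9.35e-06; adjusted p = 0.133 with an estimated correlation) and -0.05 (0.116), and in the knockdown against young HSC 0.25 (6.1e-07; adjusted p = 0.0558 with an estimated correlation) and -0.28 (1.67e-09; 0.0375). Without the sex-linked genes the mean of the lower set went from -0.446 to -0.022 in the new set (adjusted p = 0.657, with the direction of the test turned) and from -0.702 to -0.263 in the knockdown against young (1.58e-05). Across 9956 genes, which are not independent replicates, the log2 folds of Fus high against low and of age in the first set had a Pearson r of 0.384 and a Spearman rho of 0.334.

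CTCF peaks were then compared between the fractions. The Fus high lists held 11535 and 12725 peaks and the Fus low lists 7543 and 5600, a ratio of means of 1.85 (12130.0 ± 841.5 against 6571.5 ± 1373.9, SD, n = 2 each; exact permutation p = 0.333, the smallest that 2 against 2 libraries can give). Covered length was 2134.65 ± 35.6 kb against 1352.4 ± 249.6 kb. Each list ended at its own lowest total signal, 169.8 and 155.3 in Fus high and 367.8 and 566.5 in Fus low. The smallest step between peak heights was 0.73 and 0.68 in Fus high and 1.05 and 1.39 in Fus low, so the lists differ in scaling. A cut-off of 566.5 for all 4 lists, chosen after the data were seen, left 1352 and 581 peaks against 4082 and 5600. The number of sites bound in each fraction therefore cannot be compared from these lists.

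Of 24342 regions in any of the 4 lists, 2066 (8.5%) were in all 4, 595 in both Fus high and neither Fus low list, and 831 in both Fus low and neither Fus high list. These counts depend on the choice of peaks: the 595 and 831 became 316 and 981 with lists of equal length, 16 and 1912 at one cut-off, and 839 and 325 in the stronger 0.5 of each list. With 1 library left out they were 9254 and 1722 without Fus high replicate 1, 6724 and 1084 without Fus high replicate 2, 1081 and 1723 without Fus low replicate 1, and 800 and 2823 without Fus low replicate 2. The shares that follow were computed for the 595, 831 and 2066 alone. The CUT&RUN lists of other HSC, a separate assay, held the common regions (97.8% in the aged and 80% in the young list) and the Fus-low-only regions (97.5 and 73.3%) more often than the Fus-high-only regions (68.7 and 29.4%). Of the first Fus high list 29.5% of peaks recurred in the second, and 36.9 and 30.8% in the first and second Fus low lists. Of the second Fus high list 27.1% recurred in the first, and 24.6 and 21.2% in the Fus low lists. Of the first Fus low list 54.0% of peaks recurred in the second, and of the second 72.5% in the first. Gene starts within 1000 bp were found for 52.9% of the Fus-high-only, 22.9% of the Fus-low-only and 58.0% of the common regions.

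**Figure D4:**
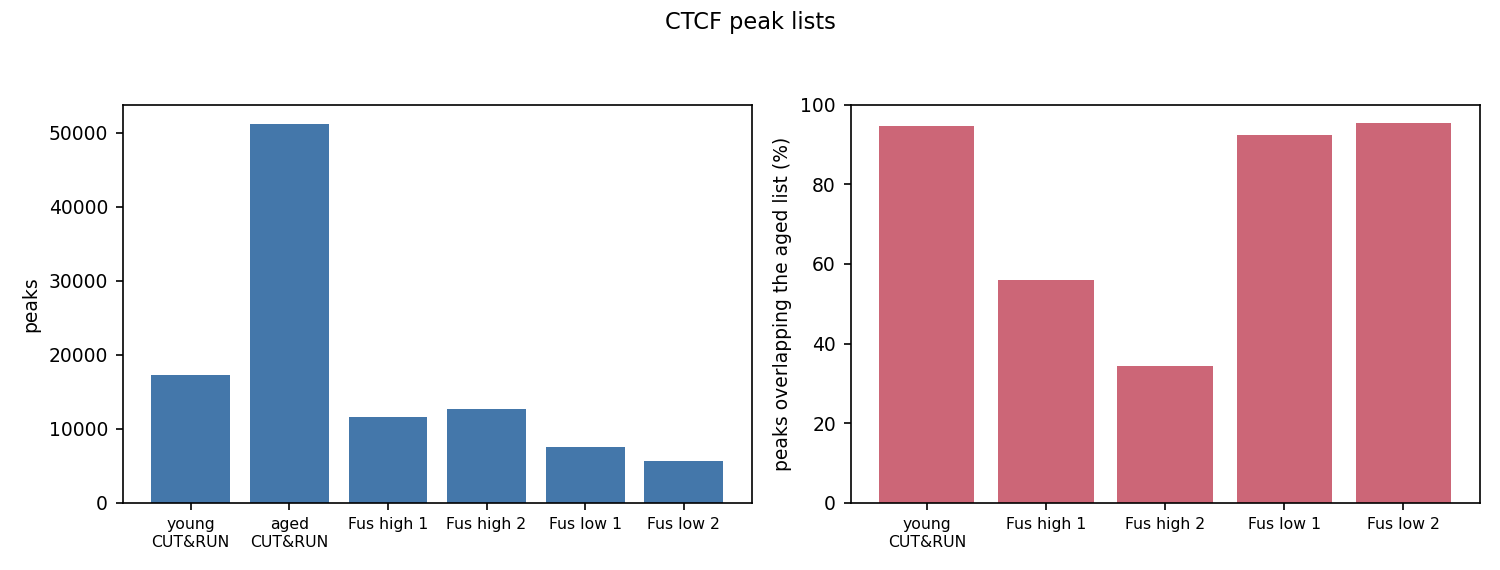
Number of CTCF peaks in each of the 6 lists (left) and percent of the peaks of each list that overlap a peak of the aged CUT&RUN list (right). The aged list is the longest with 51204 peaks, and 55.9 and 34.3% of Fus high peaks lie in it against 92.3 and 95.5% of Fus low peaks.

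Genes with a Fus-high-only peak at their start were higher in Fus high RNA (262 tested, 86 up and 29 down, median 0.16 against -0.07 for all genes, adjusted p = 0.00285; 0.00229 with an estimated correlation), and genes with a Fus-low-only peak were lower (105 tested, 11 up and 38 down, median -0.51, adjusted p = 0.00285; 0.00229 with an estimated correlation). Among the genes called in RNA, the Fus-high-only peaks with the highest total signal lay at the starts of Hist1h2an (chromosome 13, 21787206 to 21787681; log2 fold of the RNA 5.46), Rps18 (17, 33955626 to 33955923; 0.21), Stmn1 (4, 134468775 to 134469159; 2.59), a regulator of microtubules, and the neighbours Mad1l1 (1.22) and Nudt1 (5, 140321521 to 140321867). Among the called genes with a Fus-low-only peak, the peaks with the highest total signal lay at Tbc1d4 (14, 101609075 to 101609297; -0.95), Capn2 (1, 182517451 to 182517782; -0.86), Jak2 (19, 29251513 to 29251855; -0.92), a kinase of cytokine receptors, Herpud2 (9, 25151701 to 25152038; -0.85) and Elovl7 (13, 108214227 to 108214497; fell by 1.89). With each list reduced to the length of the smallest, the second relation was lost (adjusted p = 0.176) and the first held. At one cut-off of signal both were lost (adjusted p = 0.708 for Fus-low-only, and 0.882 with the direction turned for the 4 genes left as Fus-high-only).

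The aged CUT&RUN list held 51204 peaks over 9490.2 kb and the young list 17209 peaks over 2786.2 kb, without replicates. Of the young peaks 94.6% lay in the aged list, 16102 of 52033 regions (30.9%) were shared, 35010 were in the aged list only and 921 in the young list only. The lowest total signal was 122.6 in the aged and 496.6 in the young list, and at a cut-off of 496.6 the aged list held 16485 peaks against 17209. The smallest step between peak heights was 0.4 in the aged and 1.53 in the young list, so the lists differ in scaling. The number of sites bound at each age therefore cannot be compared from these lists. Genes with an aged-only (4150) or young-only (87) peak at their start did not differ from other genes in the first ageing set (adjusted p = 0.972 for both) or in the new one (0.966 and 0.797). Xist had an aged-only peak at its start (chromosome X, 103484084 to 103484330).

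In the Hi-C library of aged HSC, contacts crossed CTCF peaks less often than nearby sites. The file held 16363720 read pairs, 78.01% of them within 1 chromosome (77.99 to 78.03) and 51.39% (51.37 to 51.42) within a chromosome and over 20 kb apart. Within 100 kb of aged CTCF peaks 26.97% of pairs (26.94 to 27.0) crossed the peak, against 29.32% (29.29 to 29.35) at sites moved by 200 kb, a ratio of 0.92, lower on 20 of 20 chromosomes. At peaks shared with the young list the ratio was 0.842 (24.89 against 29.55%), at aged-only peaks 0.95 (27.76 against 29.24%) and at young-only peaks 0.979 (28.40 against 29.00%, lower on 13 of 20 chromosomes). No other Hi-C library was analysed here, so these shares were not compared between groups.

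**Figure D5:**
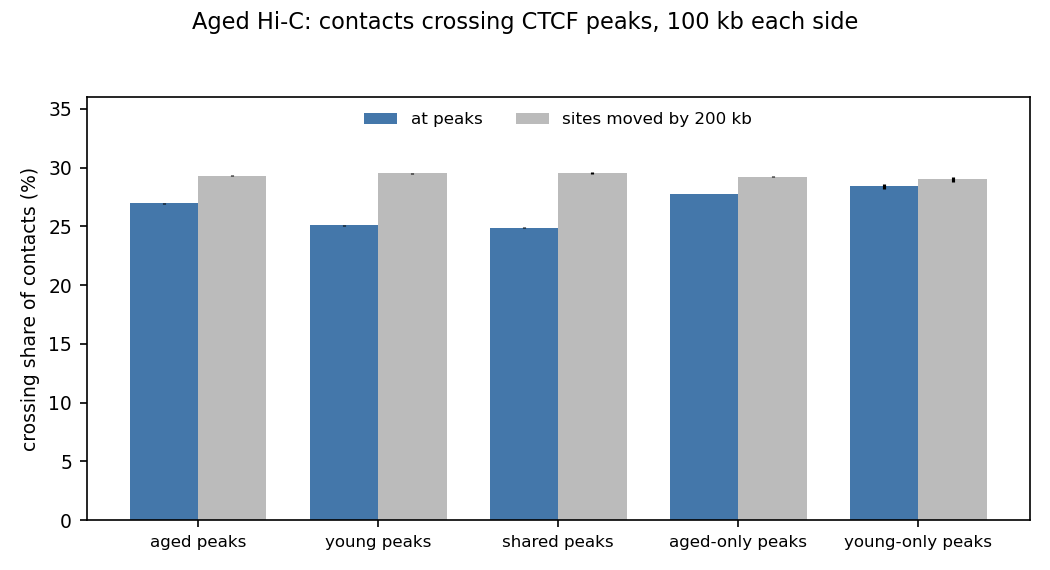
Percent of Hi-C pairs of the aged library that cross a CTCF peak within 100 kb, and the percent at sites moved by 200 kb, for 5 sets of peaks, with 95% intervals of the counts. The crossing percent at shared peaks is 24.89 against 29.55 at moved sites, and at young-only peaks 28.40 against 29.00.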

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

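The tests weighed for the first 3 patterns and the splits of the libraries were chosen after the results were seen, except the share of CTCF peaks on the Y chromosome, whose outcomes were written down first. The test of the difference between the ageing sets was fixed beforehand.

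Cell-cycle genes were higher in the libraries labelled Fus high, with a median log2 fold of 4.69 over the G2/M genes. The groups differ in the share of reads outside genes, but with that share as a covariate 22 of 22 G2/M genes were still called at a median of 4.69, which argues against it as the whole cause. B-lineage cells among the sorted cells could bring cycling transcripts: over the 9 Fus high libraries the B marker and G2/M levels had a Pearson r of 0.65 (exact permutation p = 0.093) and a Spearman rho of 0.83 (exact permutation p = 0.008), and r was 0.71 over the 7 libraries left without the 2 farthest ones. This was the 1 relation of its kind computed, and it does not decide between B-lineage cells and cells that divide and prime together, with Cd79a at 1000.0 CPM although the Lineage- gate would remove cells that bear mature B cell antigens. A biological difference between cells with more and less Fus protein stays open, as does a difference in cell composition between the 2 gates.

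Xist and Y-linked genes differed between aged and young RNA libraries. In 15 of 15 libraries the counts went with female animals among the aged and knockdown libraries (Xist from 110.57 to 671.77 CPM, Y-linked genes at most 1.06 CPM) and male animals among the young ones (Y-linked genes from 121.07 to 151.4 CPM, Xist at most 4.07 CPM), so a difference in sex is a likely source of these genes' change. For the CUT&RUN libraries the aged share of peaks on the Y chromosome was 0.84 of the young share, which met the outcome written beforehand for animals of 1 sex. That outcome was wrongly chosen, since 23 of 24 young and 54 of 60 aged Y peaks lie past 90000000 bp, at the end of the chromosome that holds sequence shared with the X chromosome, so the sex of those animals cannot be told from it. Age, sex and the 2 together stay open for every autosomal gene that differed between aged and young RNA.

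Haemoglobin RNA was higher in the new aged libraries than in the young or knockdown ones. Hbb-bs stood at 2790 CPM in aged, 6.034 CPM in young and 6.803 CPM in knockdown libraries, whereas Hbb-bt stood at 739.3, 5.544 and 118 CPM and so was also higher in the knockdown than in young. If progenitors that carry the whole erythroid list were the source, its 8 other markers should have fallen with globin in the knockdown, but 5 had positive folds there and the median log2 fold was 1.59 (interquartile half-range 1.46), while Hbb-bs fell by 8.69. Alas2, an enzyme of haem synthesis, went the other way and fell with globin (log2 fold -6.341). It stood at 14.71 to 314.35 CPM in aged and 0.45 to 4.25 CPM in knockdown libraries, without TMM scaling. Slc4a1 (-2.26) and Gypa (-0.33) also had negative folds. Later erythroid precursors therefore stay open. RNA of mature red cells stays open too. The ratio of alpha to beta globin counts varied little between the 3 aged libraries (highest over lowest 1.23), but precursors would show the same, and the 7 erythroid markers other than globin and Alas2 had a median log2 fold of 2.29 in aged against young, so the 2 sources cannot be told apart. An effect of age or of the knockdown on globin genes in HSC stays open and was not tested.

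Other splits of the same libraries were run for each count of called genes. For Fus high against low 1 of 100 splits, the real one with 4686 genes, gave as many, and the highest of the others gave 2. This excludes chance assignment only if the libraries are independent units. The labels do not tie libraries to animals, so that is not known. With 3 against 3 libraries only 10 splits exist, too few for a share under 0.05: the real split, 1 of the 10 each time, gave 4, 7, 8 and 12 genes for the first ageing set, the new ageing set and the knockdown against aged and young, and the highest other gave 0. For the difference between the ageing sets, 6 of 100 splits gave as many genes as the real 4 and the highest other gave 9, so chance cannot be excluded for that count.

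The test of the difference between the ageing effects of the sets, with the limit just given, passed for Txnip (adjusted p = 0.02796), Mfsd2b (0.02796), Bub1 (0.03292) and Tedc1 (0.04007). It also passed for the lists of genes that rise in aged HSC (adjusted p = 0.0123 with an estimated correlation), megakaryocyte and platelet genes (0.0202) and G1/S genes (0.00819). A further 6 lists, G2/M among them (3.05e-18), passed with the preset correlation and not with an estimated one (0.0629 to 0.824).

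Single libraries stood apart from the other 8 of their group in 19 of 106 sets of values checked, where chance gives about 1 in 20 for normally spread values. That rate does not hold for genes near 0, where a few reads in 1 library set the measure. The measure is the gap to the nearest library over the whole range. Among Fus low libraries it was 1.0 for Bcat1 in 30-1, 1.0 for Mxd3 in 30-4 and 1.0 for Efcab11 in 36-1, genes at 0 in all others of the group. It was 0.78 for Eme1 in 30-5, 0.86 for Neil3 in 36-6, 0.54 for Igdcc4 in 32-6, 0.62 for Tcp11l2 in 32-3 and 0.59 for Batf2 in 36-1. Library 36-6 held the highest Fus value, 180.7 CPM (0.55), and the most detected genes, 12780 (0.56), and 30-4 the highest share of reads outside genes, 25.7% against 19.9% in the next (0.54). Among Fus high libraries it was 0.56 for Eme1 in 30-3, 0.8 for Meg3 and 0.54 for Clec1a in 32-1, 0.82 for Unc45b in 32-6, 0.53 for the G2/M mean in 36-3 and 0.56 for the interferon response mean in 32-1. Library 30-3 had the lowest B marker mean (0.57) and the most Malat1, a nuclear noncoding RNA, at 4725 CPM against 2152 CPM in the next (0.73). Malat1 also differed between the groups, at 3093.7 to 6223.5 CPM in Fus low and 1197 to 4725 CPM in Fus high libraries.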

How the results depend on the processing

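Alternatives chosen after the data were seen were the covariate, the left-out libraries 30-3, 30-4 and 36-6, the single cut-off of peak signal, the estimated correlation at gene starts, the blocks and left-out libraries for lists and for the difference between sets, and the ageing sets without sex-linked genes or members of the cell-cycle lists. Of the counts and tests that answer a comparison, 113 alternative values were on the same side and within 1.5 times, 47 weaker, 14 stronger, 3 moved and 5 reversed. Of the values of named genes 870 kept direction and call, 207 lost and 28 gained the call and 7 reversed, and for lists these numbers were 736, 69, 39 and 2. Except where construction shows it (fewer libraries, fewer genes or fewer peaks), the cause was not tested.

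For Fus high against low the 4686 calls became 1927 with the covariate, and from 3374 to 6112 under all other alternatives run. DESeq2 called 627 genes in the first ageing set, 132 in the new set, 319 and 280 for the knockdown against aged and young, and 295 for the difference between sets. Without a filter on low counts the knockdown against young had 23 and the difference between sets 14 calls, and with only the 2 groups in the fit the knockdown against aged had 3. With 1 library left out the calls were 0 to 1 in the first set, 4 to 9 in the new set, 0 to 8 and 2 to 5 for the knockdown against aged and young, and 0 to 24 for the difference between sets. With an estimated correlation 7 of 16 lists stayed called for Fus high against low, 2 of 10 in the first set, 1 of 5 in the new set, and 2 of 7 and 5 of 11 for the knockdown against aged and young. Left-out libraries gave 3 to 6 lists in the new set and 6 to 12 for the knockdown against aged, 12 without knockdown replicate 1. The sets of genes from the first ageing set had an adjusted p of 0.118 (lower set, knockdown against aged), 0.133 (higher set, new ageing set) and 0.0558 (higher set, knockdown against young) with an estimated correlation.

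The shared numbers in library names were not taken to pair the libraries, since no correlation of the deviations of same-numbered libraries reached 0.1 (-0.044, 0.069 and 0.033 for Fus, against -0.078 to 0.04 for different numbers). With the number as a replicate block edgeR called 0 genes in the first set, 1 in the new set, 1 and 0 for the knockdown against aged and young, 0 for the difference between sets and 4681 for Fus high against low. In 3 against 3 libraries the block takes up residual degrees of freedom.

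Directions turned for Fus in Fus high against low (log2 fold 0.137 without library 36-6 and 0.362 without number 36), for Ctcf in the new ageing set (-0.276 to 0.054 with 1 library left out, 0.111 with both sets in 1 fit) and for Fus there (0.05 in that fit), and for Ctcf in the knockdown against young (-0.072 to 0.24 with 1 library left out). None of these was called. Lymphoid priming in the first set had adjusted p from 0.0128, with the direction turned, to 0.967 with 1 library left out, and ribosomal proteins in the knockdown against aged from 3.24e-05 to 0.186, the latter with the direction turned.

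The 595 Fus-high-only CTCF regions against 831 Fus-low-only became 316 against 981 with lists of equal length and 839 against 325 in their stronger 0.5. At one cut-off, on unequal scales, they were 16 against 1912. With 1 library left out the Fus-high-only count was 800 to 9254. Aged-only regions became 4099 against 3932 young-only with lists of equal length, 17106 against 46 in the stronger part and 3695 against 4253 at one cut-off. At gene starts the adjusted p was 0.176 for Fus-low-only with lists of equal length, and 0.708 for Fus-low-only and 0.882 for Fus-high-only at one cut-off. The Hi-C ratio of 0.92 was 0.932 with 50 kb, 0.857 at the stronger peaks and 0.925 with sites moved by 500 kb. Depth limits the genes at 0 in a group, whose folds are lower bounds. Every alternative fixed beforehand gave a value.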

Other observations

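Prss50, Slc15a2, Txnip and Igkc were chosen after their values were seen, whereas the comparison of folds across genes was fixed beforehand. Prss50, a serine protease gene on chromosome 9, was on in 2 comparisons that share no library. The first sets more against less Fus protein by the label, whereas the second lowers Fus. Neither this rise nor the lower Txnip given below thus ran one way with the level of Fus. It was above every Fus low library in 9 of 9 Fus high libraries (16.24 ± 10.11 against 0.035 CPM), and it was at 33.03 to 53.45 CPM in the 3 knockdown libraries and at 0 in all aged and young libraries of the new set. Slc15a2, a peptide transporter, was at 0 in the 3 young libraries of the new set and at 29.66 ± 5.781 CPM in the aged and 30.02 ± 9.391 CPM in the knockdown libraries. In the first set it was at 10.25 ± 0.1208 CPM in aged and 11.99 ± 12.01 CPM in young (adjusted p = 0.986), and the test of the difference between the sets did not pass for it (adjusted p = 0.2419). Txnip, which fell in Fus high by 2.06 on the log2 scale (149.1 ± 42.9 against 621.3 ± 136.2 CPM, adjusted p = 3.17e-10), was lower in all 3 knockdown libraries than in all 3 aged ones (691 ± 42.84 against 1104 ± 33.5 CPM) without passing over all genes (adjusted p = 0.1538).

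Across genes the folds of the comparisons were related to different degrees, with the reserve that genes are not independent replicates. The Pearson r was 0.384 (Spearman rho 0.334) between Fus high against low and the first ageing set, but -0.022 (-0.03) between Fus high against low and the new ageing set. It was 0.192 (0.282) between Fus high against low and the knockdown against aged, 0.095 (0.015) between the 2 ageing sets and 0.019 (0.114) between the knockdown and the first ageing set. Between the knockdown against aged and the new ageing set r was -0.58 (-0.483), but these 2 share the aged libraries, and 50 simulations with the sharing alone gave -0.506 on average (-0.534 to -0.479), with a covariance of -1.119 in the data and -0.717 in the simulations. The share of genes with the same sign was 33.3% in the data and 33.22% in the simulations.

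Igkc, the immunoglobulin kappa constant gene of B-lineage cells, reached 60000 CPM in Young replicate 1 and 27430 CPM in Young replicate 3 of the first set and 2.183 CPM in Young replicate 2, and 7462 CPM in Aged replicate 2 against 47.91 and 16.01 CPM in the other 2 aged libraries. The 10 highest genes of the young libraries of that set took from 23.5 to 32.2% of all counts.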
